A study of Mus musculus with 12 samples.

How the data were processed

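Total RNA of 12 mouse lung samples was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample. Per the labels, all animals were male C57BL/6 mice, wild type or nmMLCK-/-. The latter name stands for a loss of the long (non-muscle) isoform of myosin light chain kinase, which Mylk encodes. Each genotype was either left to breathe spontaneously (SB) or ventilated for 4 h with a high tidal volume to produce ventilator-induced lung injury (VILI), with 3 arrays in each of the 4 groups. The tidal volume is 40 ml/kg in the sample labels and 30 ml/kg in the series text, at 65 breaths per min and an end-expiratory pressure of 0 cm H2O. Which value was used cannot be read from the data.

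The deposited values are log2 signals per probe set, already normalized between arrays by the authors, who name MAS5 and GCRMA without stating the part or version of each. The range of the values, 0.7505 to 16.29 with array medians of 4.94 to 5.037, is that of a GCRMA-type summary on a log2 scale. Such a summary compresses differences between dim probe sets and makes the arrays' distributions nearly equal, so a change in total RNA per cell cannot be seen. The genome build behind the probe set annotation is not given in the sources used here. The number of arrays, 3 per group, limits the precision. The median standard error of a gene's log2 difference between 2 groups was 0.148, and that of a difference of responses was 0.209.

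Of 45037 probe sets, 34945 carried 1 gene symbol in the platform's annotation, 932 carried several and 9160 carried none. Probe sets whose mean over all arrays was under the 40th percentile, a log2 signal of 3.056, were left out, which kept 22443 with 1 symbol. Each gene was represented by its probe set with the highest mean, which gave 12309 genes, 5783 of them with more than 1 probe set past the filter. Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on a model of 4 group means over all 12 arrays, with Benjamini-Hochberg adjusted p under 0.05 within each comparison. The comparisons were VILI against SB in each genotype, the difference between these responses, and knockout against wild type under SB and under VILI. Adjusted p-values below come from limma unless another test is named, and log2 differences are given with their standard error and n = 3 arrays per group.

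Before the data were examined, 30 gene lists with 443 distinct members were written, together with the tests, the alternatives and the rule for naming genes. Of the members, 412 had a named probe set and 377 were tested. A list needed 5 tested members, which 29 lists had, and the erythroid list with 4 did not. Lists were tested with camera in limma at its preset correlation of 0.01, adjusted over the 29 lists of a comparison. Camera with a correlation estimated from the data and fry, a test of whether a list's genes move on balance in 1 direction, were run beside it. The genes named are the 10 with the largest rise and the 10 with the largest fall among passing genes whose groups do not overlap, up to 4 members with the smallest p of each list described, the members of the cytokine list, and Mylk. Where fewer than 5 genes pass, the 5 with the smallest p are named. Genes named outside this rule are marked as chosen after their values were seen.

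Whether the knockout damped the response as a whole was tested over the genes called for the mean VILI effect of both genotypes. The statistic was the median of the difference between the knockout and wild-type responses, signed by the direction of the mean response. Its two-sided p came from an exact permutation of the genotype within SB and within VILI, which gives 400 arrangements. Gene positions were taken from the RefSeq annotation of GRCm38.p6 and used only for the order of neighbouring genes and for the chromosome that carries Mylk.

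The gene test, the list test and the damping test were tested on simulated data with the same number of arrays and the spread of the real genes, 10 sets each, with 200 changed genes among 12309 for the gene test. Of genes changed 2-fold, 74.93% were recovered for VILI against SB in wild type, 70.75% in knockout and 53.43% for the difference of responses, and 4-fold changes were recovered at 95.3%, 93.64% and 85.61%. In these simulated sets, between 5.181% and 6.446% of the calls were false. List shifts of 0.5 log2 were recovered for 100% of lists in the wild-type comparison and 82.76% for the difference of responses. In 10 sets with no shift, 0 lists were called in the former and 1 in the latter. Simulated genes were independent in every test, and each had the same spread in all arrays. Among the real SB arrays, an exchange of arrays between the genotypes gave up to 642 called genes. The rates of the gene test therefore do not carry over to the real data. The estimated correlation within the real lists ran from -0.031 to 0.858, so the rates of the list test do not carry over to them. With genotypes exchanged among the real arrays, up to 18 lists shifted for the difference of responses. The damping test reached p under 0.05 in 6 of 10 sets with a reduction of 0.3 log2 and in 4 of 10 sets with a reduction of 0.6 log2, at 500 independent genes. Its p lay between 0.005 and 0.1 at the former size and between 0.01 and 0.1 at the latter. By construction, exchanging the SB arrays hardly changes the statistic in such data, so near ties set p within that range. With 10 sets per size, the counts do not show how power depends on the reduction.

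Alternatives covered quantile normalization, equal array medians, no filter and a 60th percentile filter, the mean of a gene's probe sets, every probe set tested on its own, an intensity trend with robust variance, array weights, a fit of the compared groups alone, the replicate number as a block, and each array left out in turn. Alternatives chosen after seeing the data were a second estimate of the array weights, the 2 SB arrays that stand apart left out, and wild-type SB replicates 1 and 2 left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.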

Results

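The data are lung gene expression profiles of 12 mice in 4 groups of 3, wild type and nmMLCK-/- (here the knockout), each under spontaneous breathing (SB) and after ventilator-induced lung injury (VILI). The arrays correlated with each other at 0.9806 to 0.9979 across all 45037 probe sets, including those under the filter level. Probe sets are not independent replicates. The first principal component held 51.73% of the variance and separated VILI from SB. The second held 17.11% and set wild-type SB replicate 3 and knockout SB replicate 2 apart from the other 4 SB arrays. In these 2 arrays the median of the glucocorticoid response list, relative to each gene's mean, was -0.78 and -1.14, against -0.04 to 0.35 in the other SB arrays. The NRF2 and oxidative stress list stood at -1.24 and -1.58, against 0.01 to 0.26. Wild-type SB replicate 3 also had a neutrophil marker median of 1.08, where the other 5 SB arrays lay between -2.10 and -1.16 and the VILI arrays between 0.72 and 1.76. A separate difference, looked for after the values were seen, set wild-type SB replicates 1 and 2 apart from the other 10 arrays in 6 genes, Cd59a, Fank1, Mboat2, Rab4a, Sox11 and Wdfy1, and showed that Nnt splits the arrays in yet another way. Sox11 had log2 signals of 3.60 and 3.66 in these 2 arrays and 7.14 to 9.28 in the others.

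**Figure D1:**
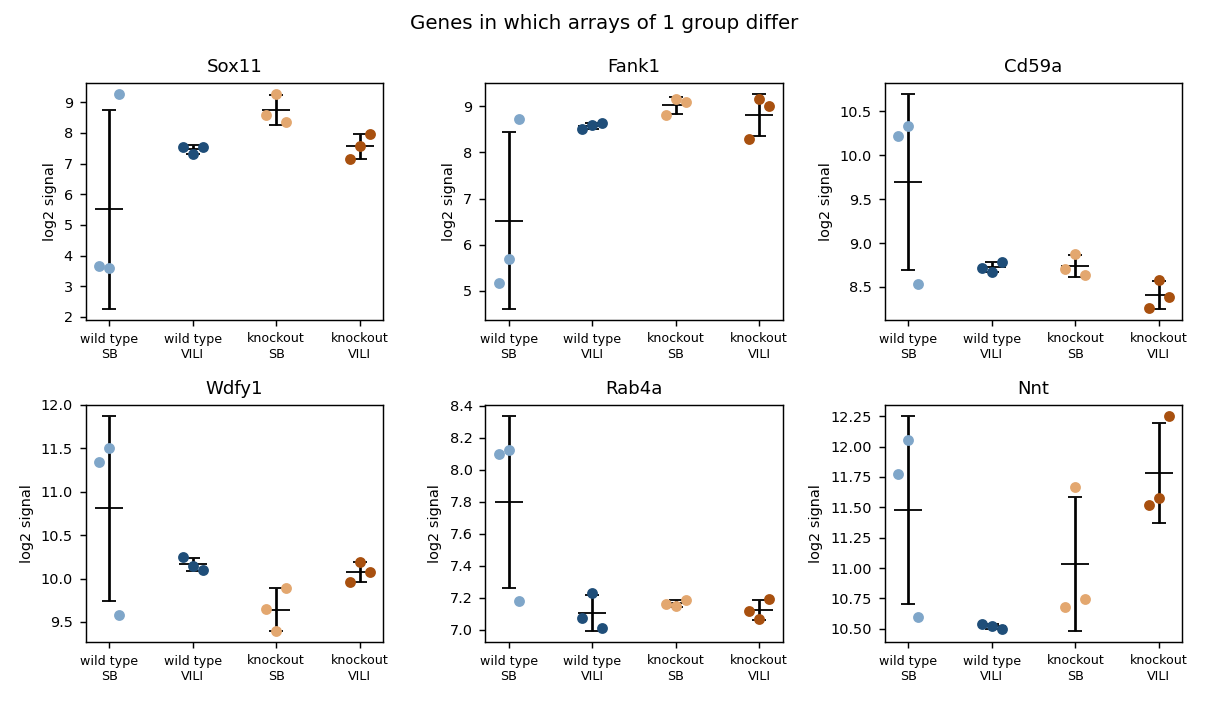
Log2 signal of Sox11, Fank1, Cd59a, Wdfy1, Rab4a and Nnt in each array, with the mean and SD of each group of 3 arrays. Points run from replicate 1 on the left to replicate 3 on the right, and in Sox11 the first 2 wild-type SB arrays lie at 3.60 and 3.66 while all other arrays lie at 7.14 or above.

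The targeted gene was read first, by 3 probe sets of Mylk. Knockout minus wild type under SB was -0.97 ± 0.47 (SE, n = 3 arrays per group), -0.70 ± 0.26 and -0.22 ± 0.08 for the 3, and none passed (limma adjusted p = 1 each). That adjustment runs over all probe sets past the filter, and the unadjusted limma p were 0.068, 0.021 and 0.018. The first probe set stood at -0.61 without wild-type SB replicate 1 and at -1.62 without wild-type SB replicate 3 (adjusted p = 0.098). Under VILI the differences were -0.74, -0.15 and -0.14, with adjusted p of 0.61, 0.89 and 0.56 (unadjusted limma p of 0.15, 0.56 and 0.11). The second stood at -0.04 without wild-type VILI replicate 1, -0.29 without wild-type VILI replicate 2 and -0.07 without knockout VILI replicate 3, and the third at -0.09 without wild-type VILI replicate 1. The files do not say which isoform each probe set reads, so these values neither show nor rule out the loss of the long isoform.

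VILI against SB in wild type asks how lungs after 4 h of high tidal volume ventilation differ from those of spontaneously breathing mice. No group was ventilated at a low tidal volume. An effect of the tidal volume therefore cannot be told apart from that of ventilation itself or the rest of the procedure. Il6, a cytokine of the acute phase response, rose by 6.89 ± 1.44 log2 (adjusted p = 0.0116). Dio2, which activates thyroid hormone, rose by 4.73 ± 0.31 (adjusted p = 4.09e-05), and the neutrophil chemoattractant Cxcl2 by 4.47 ± 0.66 (adjusted p = 0.00252). Apold1 rose by 5.57, the interleukin 1 decoy receptor Il1r2 by 4.95, Krtap17-1 by 4.87, the hyaluronan synthase Has1 by 4.58, Nfil3 by 4.03 and Prss22 by 3.86. The SB means of Il6, Cxcl2 and Has1, and the VILI mean of Smim5 named below, lie under the filter level of 3.056, so the sizes and ranks of their differences are not measured. The tight junction gene Cldn4 rose by 4.98. It lost its call in 9 of the 12 fits that each left out 1 array, with a largest adjusted p of 0.0961 without wild-type VILI replicate 1. The largest falls were in Ankrd63 (-4.04 ± 0.64, adjusted p = 0.00356), the heat shock genes Hspa1b (-3.97) and Hspa1a (-3.80), Zfp467 (-3.80), the clock output gene Dbp (-3.28 ± 0.30), 2810410L24Rik (-2.48), the ciliogenesis regulator Foxj1 (-2.47) and the endothelial transcription factor Sox18 (-2.47). Smim5 (-2.63) and Rtp3 (-2.59) also fell. Smim5 lost its call in 2 and Rtp3 in 8 of the 12 fits that left out 1 array. Their largest adjusted p was 0.0622 without wild-type SB replicate 1 and 0.117 without wild-type VILI replicate 1.

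Among the lists, NF-kB and TLR signalling feedback had 8 of 17 tested members that rose and none that fell (10 adjusted over the list alone). Among them were Bcl3 by 1.98 ± 0.15, Nfkbiz by 1.00, Il1rn by 1.72 and Cd14 by 0.82. The list's median was 0.68 (camera adjusted p = 1.12e-06; adjusted p = 0.157 with an estimated correlation). Of the 9 tested cytokines and chemokines 4 rose, Il6, Cxcl2, Cxcl5 (2.41 ± 0.49) and Cxcl1, and 5 did adjusted over the list alone, with a median of 1.86 (camera adjusted p = 0.000292; adjusted p = 0.116 with an estimated correlation). Cxcl1, at 1.86 ± 0.56 and adjusted p = 0.0499, lost its call in 10 of the 12 fits that left out 1 array, with adjusted p of 0.107 without wild-type SB replicate 3 or wild-type VILI replicate 1, and its value was 1.13 without the latter. Without wild-type VILI replicate 1 the list's median was 1.13 as well. Il1b, at 2.09 ± 0.73, did not pass (adjusted p = 0.0791) and passed without wild-type SB replicate 3, at 3.17 and adjusted p = 0.00078. Cxcl3 (0.52, and 0.34 without wild-type VILI replicate 3), Lif (0.40, and 0.24 without wild-type SB replicate 2), Il1a (0.32) and Csf2 (-0.22, and -0.10 without wild-type SB replicate 3) did not pass either. Il1a stood at 0.18 without wild-type SB replicate 2, 0.51 without wild-type SB replicate 3 and 0.20 without wild-type VILI replicate 2. The IL-6 and STAT3 acute phase list had 4 of 16 members that rose (5 adjusted over the list alone), with Socs3 at 1.94 ± 0.18 and Pim1 at 1.00. Its median was 0.45 (camera adjusted p = 0.000143; adjusted p = 0.186 with an estimated correlation). Hypoxia response had 4 of 11 (5 adjusted over the list alone), with Adm at 2.23, Slc2a1 at 0.91 and Ndrg1 at 0.89. Its median was 0.31 (camera adjusted p = 0.00323; adjusted p = 0.116 with an estimated correlation). EGFR ligands and prostaglandin synthesis had 3 of 9 that rose (5 adjusted over the list alone; median 0.91, camera adjusted p = 0.00201; adjusted p = 0.116 with an estimated correlation).

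Immediate early genes had 4 members that rose and 1 that fell of 23 (6 and 1 adjusted over the list alone), with Myc at 2.29 and Fosl1 at 3.82 (median 0.53, camera adjusted p = 0.000694; adjusted p = 0.413 with an estimated correlation). The median was 0.30 without wild-type SB replicate 2. Neutrophil markers had 5 of 13 that rose (7 adjusted over the list alone) and a median of 1.51 (camera adjusted p = 0.000143; adjusted p = 0.367 with an estimated correlation). Without wild-type SB replicate 3, whose neutrophil markers stood at the level of the VILI arrays, that median was 2.44, and it was 0.98 without wild-type SB replicate 1. Mmp8 rose by 3.22, Trem1 by 2.24 and Clec4e by 3.41, and each lost its call without wild-type SB replicate 1, at adjusted p of 0.0845, 0.0658 and 0.115. Coagulation and fibrinolysis had 4 that rose and 1 that fell of 11 (6 and 1 adjusted over the list alone), with the urokinase receptor Plaur at 1.74, Fgl2 at 0.99 and the anticoagulant receptor Thbd at -0.47. The median was 0.24 (camera adjusted p = 0.0169; adjusted p = 0.3 with an estimated correlation). Extracellular matrix and fibroblasts had 4 of 13 that rose (5 adjusted over the list alone), with Tnc at 1.68 and Col1a1 at 0.83. The median was 0.15 (camera adjusted p = 0.0117; adjusted p = 0.367 with an estimated correlation), and the list's call was lost without wild-type VILI replicate 1 at adjusted p = 0.0604. Alveolar macrophage markers had 3 of 11 that rose, also 3 adjusted over the list alone, with Marco at 2.31 (adjusted p = 0.0619 without wild-type VILI replicate 2) and Cd68 at 0.79 (0.12 without wild-type SB replicate 1). Their median was 0.33 (camera adjusted p = 0.00634; adjusted p = 0.367 with an estimated correlation).

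Leukocyte adhesion had 2 of 14 members that rose, Selp by 1.91 (adjusted p = 0.0539 without wild-type SB replicate 1) and Cd44 by 0.62, also 2 adjusted over the list alone. Its median was 0.51 (camera adjusted p = 0.00549; adjusted p = 0.489 with an estimated correlation), and 0.29 with adjusted p = 0.0527 without wild-type SB replicate 2. T and NK cell markers had none of 12 that passed, 0 adjusted over the list alone, at a median of 0.38 (camera adjusted p = 0.0206; adjusted p = 0.407 with an estimated correlation). That list call was lost without wild-type SB replicate 2 (median 0.13, adjusted p = 0.142) and without wild-type VILI replicate 1 (median 0.13, adjusted p = 0.109), and the median was 0.24 without wild-type SB replicate 1 and 0.71 without wild-type SB replicate 3. Ciliated cell markers were the list that shifted down, with 6 of 9 that fell (9 adjusted over the list alone), among them Foxj1, Tekt4 at -2.19 and Dynlrb2 at -0.67. The median was -0.67 (camera adjusted p = 0.000135; adjusted p = 0.3 with an estimated correlation). The circadian clock list moved both ways and did not shift by camera (camera adjusted p = 0.0838), though it passed fry (fry adjusted p = 0.00203). In it 2 members rose and 7 fell, the same counts adjusted over the list alone, with the activator Arntl at 3.26 ± 0.36 and the outputs Dbp, Per3 (-2.41) and Hlf (-1.69). Heat shock and unfolded protein response had 1 that rose and 6 that fell of 16, with Dnajb1 at -1.80, and endothelial markers and junctions had 3 that rose and 4 that fell of 19, with Ramp2 at -0.92 and Angpt1 at -0.57. By camera these lists did not shift (camera adjusted p = 0.12 and 0.189). The endothelial list passed fry (fry adjusted p = 0.00465), and the heat shock list did not (fry adjusted p = 0.0518).

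In all, 1892 of 12309 genes changed in wild type, 780 higher and 1112 lower, and 486 of them by at least 2-fold, 220 higher and 266 lower. With array medians set equal, 977 were higher and 851 lower, and with quantile normalization 827 and 965, so the split depends on the scaling. The count was 933 without wild-type SB replicate 1, 1118 without wild-type VILI replicate 1, 1136 without replicate 2 and 1090 without replicate 3. Of the 917 called genes with several probe sets, 154 had probe sets that differed in sign.

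VILI against SB in knockout asks the same of the nmMLCK-/- lung. The neutrophil collagenase Mmp8 rose by 5.97 ± 0.79 log2 (62.67-fold, adjusted p = 0.00151), Il1r2 by 5.90 ± 0.83 (adjusted p = 0.00197), Slfn4 by 5.64 ± 1.23, and the myeloid lectins Clec4d and Clec4e by 4.77 and 4.34. The SB mean of Clec4e lies under the filter level, so the size of its difference is not measured. Krtap17-1 rose by 5.02, Apold1 by 4.83, Stfa2l1 by 4.74 and Prss22 by 4.13. Cldn4 rose by 5.63 and lost its call in 4 of the 12 fits that left out 1 array, with a largest adjusted p of 0.0736 without knockout SB replicate 2. The largest falls were Ankrd63 (-3.69 ± 0.64, adjusted p = 0.00495), Zfp467 (-3.42), Hspa1b (-2.71), the axonemal gene Tekt4 (-2.65 ± 0.23, adjusted p = 2e-04), Tppp (-2.44), Klhdc1 (-2.42) and L3hypdh (-2.39). Hspa1a (-2.62), Smim5 (-2.60) and Rfxank (-2.32) also fell, and lost their calls in 5, 1 and 3 of the 12 fits that left out 1 array. Their largest adjusted p was 0.066 without knockout SB replicate 3, 0.0532 without knockout VILI replicate 2 and 0.0657 without knockout SB replicate 2.

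Neutrophil markers had 10 of 13 members that rose (11 adjusted over the list alone), with S100a8 at 3.27 ± 0.54 and S100a9 at 3.60 ± 0.62. Their median was 3.25 (camera adjusted p = 5.05e-08; adjusted p = 0.324 with an estimated correlation). The IL-6 and STAT3 acute phase list had 6 of 16 (9 adjusted over the list alone), with Socs3 at 1.84 and Pim1 at 1.16. The median was 0.62 (camera adjusted p = 6.81e-06; adjusted p = 0.324 with an estimated correlation). NF-kB and TLR signalling feedback had 6 of 17 that rose, and 6 that rose with 1 that fell adjusted over the list alone, with Bcl3 at 2.23 and Myd88 at 0.65. The median was 0.52 (camera adjusted p = 4.67e-05; adjusted p = 0.324 with an estimated correlation). Immediate early genes had 7 that rose and 1 that fell of 23 (9 and 1 adjusted over the list alone), with Myc at 1.85 and Fosl2 at 1.27. Their median was 0.76 (camera adjusted p = 6.85e-05; adjusted p = 0.377 with an estimated correlation). Leukocyte adhesion had 5 of 14 that rose (8 rose and 2 fell adjusted over the list alone), with Cd44 at 0.63 and Selp at 1.63, the latter at adjusted p = 0.0761 without knockout VILI replicate 2. The list's median was 0.55 (camera adjusted p = 0.00325; adjusted p = 0.486 with an estimated correlation). Ciliated cell markers had 5 of 9 that fell (7 adjusted over the list alone), with Dynlrb2 at -0.54 and Foxj1 at -1.54, the latter at adjusted p = 0.0932 without knockout VILI replicate 2. The list's median was -0.54 (camera adjusted p = 0.00192; adjusted p = 0.377 with an estimated correlation).

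Of the 9 cytokines and chemokines, 3 rose in knockout, Il1b by 3.13 ± 0.73, Cxcl2 by 2.17 ± 0.66 and Cxcl1 by 1.79 ± 0.56, and 5 rose with 1 that fell adjusted over the list alone. The median was 0.44 (camera adjusted p = 0.017; adjusted p = 0.324 with an estimated correlation). Cxcl1 and Cxcl2 lost their calls in 8 and 10 of the 12 fits that left out 1 array, with largest adjusted p of 0.159 without knockout VILI replicate 2 and 0.123 without knockout VILI replicate 1. Without knockout VILI replicate 3 the Cxcl2 value was 1.43 and Il1b had adjusted p = 0.052. Il6 was higher by 4.43 ± 1.44 and did not pass (adjusted p = 0.052). In knockout VILI replicate 3 its signal was 2.25, near the SB arrays, and without that array it passed at 6.56 and adjusted p = 0.00103. The SB means of Cxcl2 and Il6 lie under the filter level in knockout too. Cxcl5 was higher by 0.37 ± 0.49 (adjusted p = 0.617) and by 0.22 without knockout VILI replicate 2. Lif (0.44), Cxcl3 (0.39, and 0.11 without knockout VILI replicate 3), Il1a (0.34, and 0.21 without knockout VILI replicate 2) and Csf2 (-0.64) did not pass, and Csf2 is the member that fell over the list alone. Lif passed without wild-type SB replicate 2 (adjusted p = 0.0451), and Csf2 passed at -0.87 without knockout SB replicate 3 (adjusted p = 0.0271) and stood at -0.32 without knockout SB replicate 2. Mesothelial and adipose markers had 2 of 5 that rose, Msln by 1.14 and Lrrn4 by 1.00, and 3 adjusted over the list alone (median 0.84, camera adjusted p = 0.0378; adjusted p = 0.365 with an estimated correlation). Lrrn4 had adjusted p = 0.0566 without knockout VILI replicate 2, and the list had 0.0871 without knockout SB replicate 3 and 0.0549 without wild-type VILI replicate 1. NRF2 and oxidative stress had 2 of 15 that rose, also 2 adjusted over the list alone, with Mt1 at 2.37 and Mt2 at 2.90 (0.0674 without knockout VILI replicate 2), and a median of 0.67 (camera adjusted p = 0.0282; adjusted p = 0.701 with an estimated correlation). Without knockout SB replicate 2, the array with low NRF2 genes, that median was 0.13 at adjusted p = 0.244.

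EGFR ligands and prostaglandin synthesis had 2 of 9 that rose in knockout, Has1 by 3.29 and the EGFR ligand Hbegf by 1.10, also 2 adjusted over the list alone (median 0.40, camera adjusted p = 0.0378; adjusted p = 0.324 with an estimated correlation). Its call was lost without knockout SB replicate 1 (0.0583), knockout VILI replicate 1 (0.0943) or knockout VILI replicate 2 (0.0601), and the median was 0.74 without knockout SB replicate 3 and 0.79 without knockout VILI replicate 3. T and NK cell markers had 1 of 12 that rose and 0 adjusted over the list alone (median 0.59, camera adjusted p = 0.0205; adjusted p = 0.385 with an estimated correlation). The circadian clock list again did not shift (camera adjusted p = 0.474), with Arntl at 1.54 (adjusted p = 0.0585 without knockout SB replicate 2) and Dbp at -2.32. Outside the lists that shifted by camera, Plaur rose by 1.44 and the alveolar type 1 marker Pdpn by 0.68. Angpt1 and Jam2, members of the endothelial markers and junctions list, stood at -0.91 and -0.99, and all of these genes were past the threshold. In all, 2554 genes changed in knockout, 999 higher and 1555 lower, 573 of them by at least 2-fold, 257 higher and 316 lower. With array medians set equal, 1189 were higher and 1276 lower. The count was 1308 without knockout SB replicate 2, 1553 without knockout VILI replicate 1, 1232 without replicate 2 and 1647 without replicate 3. Of the 1238 called genes with several probe sets, 324 had probe sets that differed in sign.

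**Figure D2:**
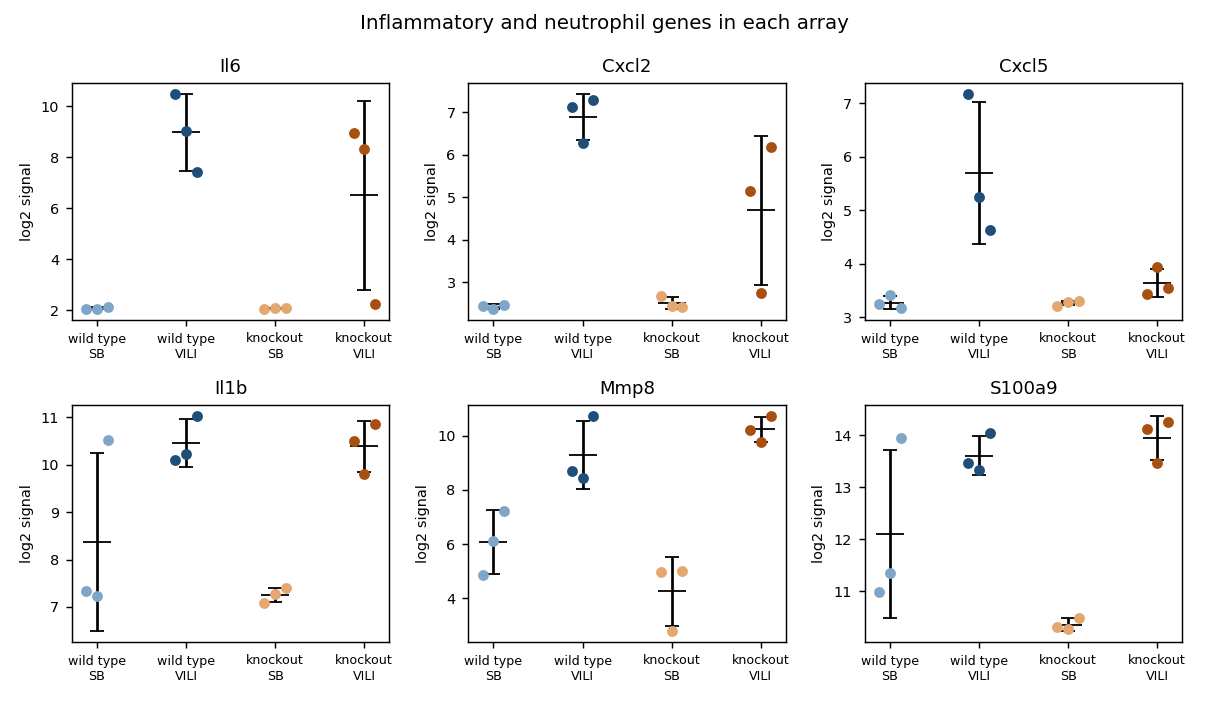
Log2 signal of Il6, Cxcl2, Cxcl5, Il1b, Mmp8 and S100a9 in each array, with the mean and SD of each group of 3 arrays. Il6 in knockout VILI replicate 3 lies at 2.25, near the SB arrays, and Il1b and S100a9 in wild-type SB replicate 3 lie at 10.53 and 13.96, with the VILI arrays.

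The difference of the VILI response, knockout minus wild type, asks whether the genotype shapes the response. No gene passed in limma, with 619 at an unadjusted p under 0.05 where 615.4 would be expected by chance. The 5 genes with the smallest p, given as values that did not pass, were Tbrg3 (0.84 ± 0.11, adjusted p = 0.244), Spin4 (-0.89 ± 0.14), Pdpn (0.80 ± 0.13), Ikzf4 (-0.74 ± 0.13) and Clec1b (1.11 ± 0.19), the last 4 at adjusted p = 0.345. The chemokines Cxcl2 and Cxcl5 had differences of -2.29 ± 0.94 and -2.04 ± 0.70, Il6 -2.47 ± 2.03 (-0.34 without knockout VILI replicate 3) and Il1b 1.05 ± 1.03, with adjusted p between 0.902 and 0.982. Cxcl2 stood at -1.32 without knockout VILI replicate 2, Cxcl5 at -1.29 without wild-type VILI replicate 1 and Il1b at 1.61 without wild-type SB replicate 2. As Il6 and Cxcl2 lie under the filter level under SB in both genotypes, the sizes of their differences are not measured. That Cxcl5 and Il6 passed in wild type and not in knockout is therefore not shown to be a difference between genotypes. Without wild-type SB replicate 3, 6 genes passed, Cd59a, Dzip1l, Fank1, Rab4a, Sox11 and Wdfy1, which include 5 of the 6 genes that set wild-type SB replicates 1 and 2 apart, and the Il1b difference was -0.04. Tests of 7 lists passed with no member past the threshold, and none with an estimated correlation. The responses themselves were close. Of the 3201 genes called in either genotype, 3111 (97.19%) moved the same way in both, and 498 were called higher in both (63.3 expected if independent) and 747 lower in both (140.5 expected). Across all tested genes, which are not independent, the responses correlated at 0.8302.

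**Figure D3:**
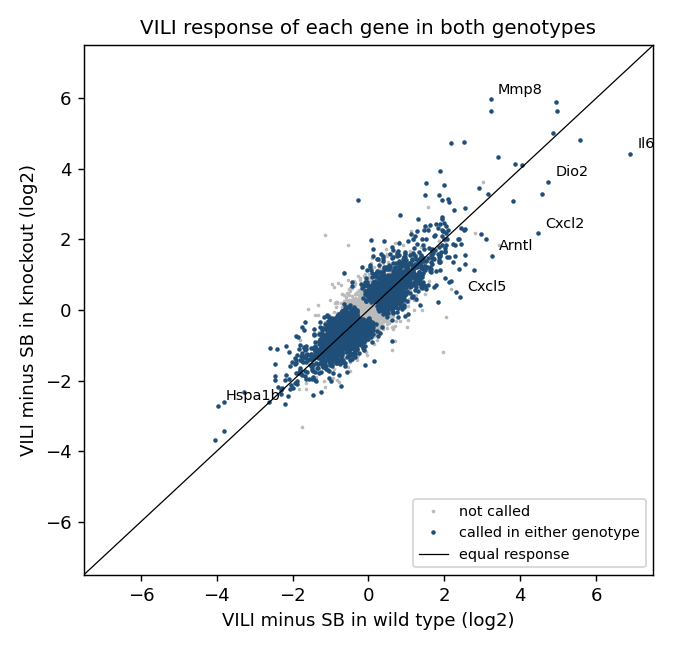
VILI minus SB in log2 for each of 12309 genes, wild type on the horizontal axis and knockout on the vertical axis, with the genes called in either genotype in blue and a line of equal response. The cloud follows the line, with Mmp8 above it and Il6, Cxcl2 and Cxcl5 below it, though none of these differences passed.

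Over the 4520 genes called for the mean VILI effect, 1739 higher and 2781 lower (2137 and 2234 with array medians set equal), the signed difference between knockout and wild-type responses had a median of 0.04 log2, 8.262% of a median response of 0.51. The exact permutation test gave p = 0.615, and 42.94% of the genes had the smaller response in knockout. The median was -0.02 without wild-type SB replicate 2 (exact permutation p = 0.755), -0.01 without knockout SB replicate 2 (exact permutation p = 0.925) and at most 0.12, without knockout SB replicate 1, in the other fits that left out 1 array. In simulated data with 500 independent genes, a reduction of 0.3 log2 reached p under 0.05 in 6 of 10 sets and a reduction of 0.6 log2 in 4 of 10. The highest p was 0.1 at both sizes, so the test can miss a damping of either size. The real genes are correlated, so these rates do not give its power in the real data.

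**Figure D4:**
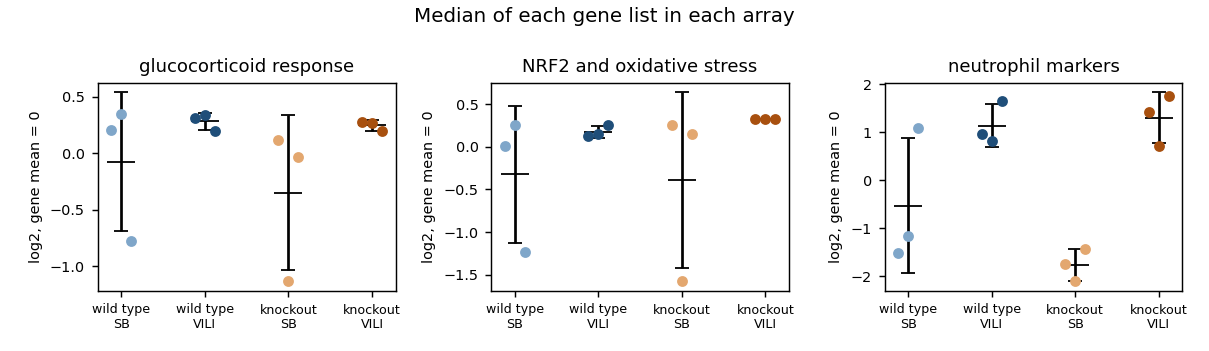
Median over the tested members of the glucocorticoid response, NRF2 and oxidative stress, and neutrophil marker lists in each array, in log2 relative to each gene's mean over all arrays, with the mean and SD of each group of 3 arrays. Wild-type SB replicate 3 and knockout SB replicate 2 lie at -0.78 and -1.14 for the glucocorticoid list, and wild-type SB replicate 3 at 1.08 for neutrophil markers.

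Knockout against wild type under SB compares the uninjured lungs. The immunoglobulin joining chain Jchain was higher by 2.44 ± 0.29 log2 (adjusted p = 0.0161) and the cation transporter Atp13a4 by 2.22 ± 0.26 (adjusted p = 0.0161). The urothelial membrane gene Upk1b stood at -2.79 ± 0.28 and the nucleotide sugar transporter Slc35a5 at -1.47 ± 0.16 (adjusted p = 0.0131 for both). The platelet receptor genes Gp1bb and Clec1b stood at -1.78 ± 0.22 (adjusted p = 0.019) and -1.12 ± 0.14 (adjusted p = 0.0161). These 6 genes, 2 higher and 4 lower, were all that changed in limma, and 4 were higher and 5 lower with array medians set equal. At an unadjusted p under 0.05 there were 460, where 615.4 would be expected by chance. The count of changed genes was 0 with only the groups compared and 0 with the replicate block. It was 0 without wild-type SB replicate 1, wild-type SB replicate 2 or knockout SB replicate 3, 16 without wild-type SB replicate 3 and 13 without knockout SB replicate 2. The adjusted p of Atp13a4, Upk1b, Slc35a5, Gp1bb and Clec1b was 0.0714 without wild-type SB replicate 1, and that of Jchain 0.0727 without knockout SB replicate 1.

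By camera 10 lists were lower in knockout under SB (6 without wild-type SB replicate 1), with no member past the threshold over all genes. Neutrophil markers had a median of -1.11 (camera adjusted p = 9.14e-07; adjusted p = 0.391 with an estimated correlation; 0 adjusted over the list alone), with Clec4d at -2.16, Mmp8 at -1.81 and S100a9 at -1.75. Clec4d and S100a9 stood at -1.25 and -0.82 without wild-type SB replicate 3, and Mmp8 at -1.07 without knockout SB replicate 2. Without wild-type SB replicate 3 that median was -0.29 at adjusted p = 0.0538, and the calls of B cell markers (-0.09, 0.651), leukocyte adhesion (-0.003, 0.886) and alveolar type 1 markers (-0.07, 0.0627) were lost too. Mesothelial and adipose markers had a median of -0.75, with Lrrn4 at -0.82, Msln at -0.75 and Upk3b at -0.86 (-0.51 without knockout SB replicate 1), and 3 that fell adjusted over the list alone (camera adjusted p = 0.000207; adjusted p = 0.288 with an estimated correlation). This list and the neutrophil, B cell and leukocyte adhesion lists kept their calls in every fit that left out 1 array other than wild-type SB replicate 3, and the mesothelial list kept it there as well. With all arrays, B cell markers had a median of -0.73 with Cd79b at -0.92 and -0.51 without wild-type SB replicate 3 (camera adjusted p = 0.000207; adjusted p = 0.397 with an estimated correlation), leukocyte adhesion -0.20 (0.000412; adjusted p = 0.429 with an estimated correlation) and alveolar type 1 markers -0.09 (0.00159; adjusted p = 0.391 with an estimated correlation). Immediate early genes had a median of -0.39 (8.72e-05; adjusted p = 0.397 with an estimated correlation), the IL-6 and STAT3 list -0.16 (0.000869; adjusted p = 0.391 with an estimated correlation) and heat shock and unfolded protein response -0.16 (0.00187; adjusted p = 0.391 with an estimated correlation). Each of these 3 lost its call without wild-type SB replicate 1, at 0.0644, 0.109 and 0.0644, and without knockout SB replicate 2, at 0.305, 0.383 and 0.541. Alveolar type 2 markers had -0.13 (0.00159; adjusted p = 0.391 with an estimated correlation), and lost the call without wild-type SB replicate 2 (-0.05, adjusted p = 0.11). Club cell markers had -0.12 (0.0144; adjusted p = 0.397 with an estimated correlation) and lost the call without wild-type SB replicate 1 (0.144), wild-type SB replicate 2 (0.235) or knockout SB replicate 3 (0.252). Where a call was kept, leaving out wild-type SB replicate 1 gave -1.97 for neutrophil markers, -0.34 for leukocyte adhesion and -0.09 for alveolar type 2 markers. Leaving out wild-type SB replicate 2 gave -0.39 for leukocyte adhesion and -0.09 for heat shock, wild-type SB replicate 3 gave -0.41 for heat shock and -0.20 for club cell markers, knockout SB replicate 1 gave -0.26 for heat shock, and knockout SB replicate 3 gave -0.29 for heat shock and -0.38 for B cell markers.

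Knockout against wild type under VILI compares the injured lungs. The immunoglobulin genes Igha and Jchain were higher by 4.66 ± 0.66 log2 (25.21-fold, adjusted p = 0.0372) and 3.11 ± 0.29 (8.63-fold, adjusted p = 0.00347). Atp13a4 was higher by 2.24 ± 0.26, Clec16a by 1.22 ± 0.18, Ammecr1 by 1.15 ± 0.17 and Tbrg3 by 0.90 ± 0.08 (adjusted p = 0.00347). The clock activator Arntl stood at -2.42 ± 0.36 (adjusted p = 0.0408), Upk1b at -2.24 ± 0.28, Dubr at -2.19 ± 0.30, the adhesion glycoprotein Vtn at -1.14 ± 0.16, Slc35a5 at -1.12 ± 0.16, Ikzf4 at -0.74 ± 0.09 and the ceramide synthase Cers3 at -0.72 ± 0.10. These 13 genes, 6 higher and 7 lower, were all that changed in limma, with 1070 at an unadjusted p under 0.05 where 615.4 would be expected by chance. Jchain and Atp13a4 were higher, and Upk1b and Slc35a5 lower, under SB as well. Igha, Dubr and Clec16a did not pass under SB but differed in the same direction there. Their SB means in wild type and knockout were 9.592 and 12.625, 10.785 and 8.83, and 7.353 and 8.547. Arntl, Vtn, Ammecr1, Tbrg3, Ikzf4 and Cers3 had closer SB means, from Arntl at 4.872 and 4.162 to Ikzf4 at 3.827 and 3.829. Jchain and Tbrg3 passed in all 12 fits that left out 1 array, with a largest adjusted p of 0.0387, and each of the other 11 genes lost its call in 6 to 11 of them. The count was 2 without wild-type VILI replicate 2 or 3 or knockout VILI replicate 2, 3 without wild-type SB replicate 1, wild-type VILI replicate 1 or knockout VILI replicate 1, 4 without knockout SB replicate 3 or knockout VILI replicate 3, and 7 without knockout SB replicate 1.

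**Figure D5:**
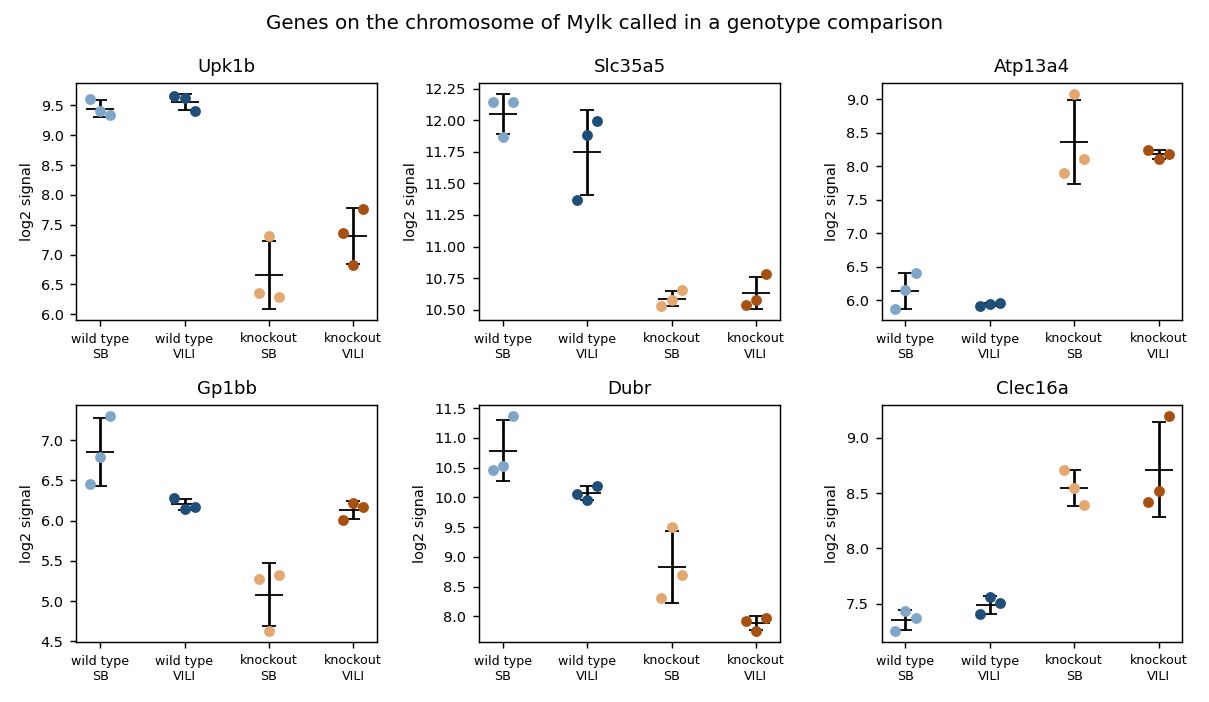
Log2 signal of Upk1b, Slc35a5, Atp13a4, Gp1bb, Dubr and Clec16a, the 6 genes on the chromosome that carries Mylk that passed in a genotype comparison, in each array with the mean and SD of each group of 3 arrays. Except in Gp1bb, where the groups meet under VILI, the knockout and wild-type arrays lie apart under both conditions.

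The list of extracellular matrix and fibroblast genes was lower in the injured knockout lungs, with a median of -0.24 and no member past the threshold over all genes (camera adjusted p = 0.0211; adjusted p = 0.419 with an estimated correlation), 1 that fell adjusted over the list alone, and adjusted p = 0.0512 without wild-type VILI replicate 1. The number of shifted lists, 1, was between 3 and 7 without any 1 of the 6 VILI arrays or of the 3 wild-type SB arrays, and 7 without knockout VILI replicate 1. Fbln1 stood at -0.64 and Lum at -0.95, the latter at -0.57 without wild-type VILI replicate 1 and -0.51 without knockout VILI replicate 3. The circadian clock list did not shift by camera (camera adjusted p = 0.0523), with 1 of 14 members that fell, Arntl, and 6 that rose and 2 that fell adjusted over the list alone. Camera asks for a shift in 1 direction, so it cannot show a change in which members move opposite ways. The mixed form of fry, which counts changes in either direction, gave an unadjusted p of 5.67e-05. Hlf stood at 1.69 ± 0.30, Per3 at 1.43 ± 0.33, Dbp at 1.35 ± 0.30, Tef at 0.83 ± 0.15 and Clock at -0.46 ± 0.10, none of which passed over all genes. The cytokine list did not shift either (camera adjusted p = 0.0523), with Cxcl2 at -2.20 ± 0.66 and Cxcl5 at -2.05 ± 0.49 (adjusted p = 0.392 and 0.326) and 2 that fell adjusted over the list alone. Cxcl2 stood at -1.23 without knockout VILI replicate 2 and Cxcl5 at -1.30 without wild-type VILI replicate 1.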

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

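The results here are 7 gene lists that passed camera, at its preset correlation, on knockout response minus wild-type response. None passed with an estimated correlation or with fry, and no single member passed over all genes. The number of lists was 2 without knockout VILI replicate 1, 3 without wild-type VILI replicate 2 or knockout SB replicate 3, 4 without knockout VILI replicate 2 and 11 without knockout SB replicate 2. The fits without both SB arrays that stand apart, and without wild-type SB replicates 1 and 2, are tests chosen after the result was seen.

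Neutrophil markers had the largest median difference, 1.094 (camera adjusted p = 0.000216; adjusted p = 0.522 with an estimated correlation; 0 of 13 adjusted over the list alone). Ngp stood at 3.27, Mmp8 at 2.75 and S100a9 at 2.09, the last at 1.16 without wild-type SB replicate 3. In wild-type SB replicate 3 the list's level was 1.08, against -2.10 to -1.16 in the other SB arrays. The median was 0.883 without that array (adjusted p = 0.0286), 1.74 without wild-type SB replicate 1 and 1.70 without knockout SB replicate 1. As a share of the median with all arrays it was 0.8078 without wild-type SB replicate 3 and 0.865 to 1.589 with another array left out (SD 0.2564). Without both SB arrays that stand apart it was 0.393, a share of 0.3594, at adjusted p = 0.0523.

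Alveolar type 1 markers had a median of 0.127 (camera adjusted p = 0.0158; adjusted p = 0.522 with an estimated correlation; 1 rose adjusted over the list alone), with Pdpn at 0.80. The call was lost without knockout VILI replicate 1 (adjusted p = 0.136), and the median was 0.08 without wild-type SB replicate 3, 0.08 without wild-type VILI replicate 3 and 0.07 without knockout SB replicate 1. Mesothelial and adipose markers had a median of 0.793 (camera adjusted p = 0.0215; adjusted p = 0.494 with an estimated correlation; 1 rose adjusted over the list alone), with Msln at 1.08. That call was lost without knockout SB replicate 3 (0.0995) and without knockout VILI replicate 1 (0.057). The list lay at -0.86 and -0.74 in knockout SB replicates 1 and 3, and at 0.05 in replicate 2.

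Alveolar macrophage markers had a median of -0.206 (camera adjusted p = 0.0354; adjusted p = 0.522 with an estimated correlation; 0 adjusted over the list alone), with Cd68 at -0.99 and Marco at -1.79 (-1.18 without wild-type SB replicate 1). The call was lost without wild-type SB replicate 3 (0.0825), wild-type VILI replicate 2 (0.116), knockout SB replicate 3 (0.164), knockout VILI replicate 2 (0.0584) or knockout VILI replicate 3 (0.07). The median was -0.35 without wild-type SB replicate 1, -0.34 without wild-type VILI replicate 1 and -0.43 without knockout SB replicate 2. B cell markers had a median of 0.689 (camera adjusted p = 0.0492; adjusted p = 0.594 with an estimated correlation; 0 adjusted over the list alone), with Cd79b at 0.91 (0.51 without wild-type SB replicate 3). The list's level was 1.22 in wild-type SB replicate 3 and -1.05 to 0.32 in the other arrays, and without that array its median was -0.03 (adjusted p = 0.779). The call was also lost without wild-type VILI replicate 2 (0.0745) or 3 (0.0923), knockout SB replicate 1 (0.11) or 3 (0.166), and knockout VILI replicate 1 (0.184) or 2 (0.052), and the median was 1.05 without wild-type SB replicate 1.

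The circadian clock list had a median of 0.254 (camera adjusted p = 0.0492; adjusted p = 0.494 with an estimated correlation; 2 rose and 1 fell adjusted over the list alone), with Arntl at -1.71, Hlf at 1.36 and Tef at 0.74. The call was lost without wild-type SB replicate 1 (0.126) or 2 (0.122), wild-type VILI replicate 2 (0.0745), knockout SB replicate 1 (0.0709), 2 (0.115) or 3 (0.0705), or knockout VILI replicate 1 (0.144) or 2 (0.0757), and the median was 0.40 without wild-type SB replicate 3. The hypoxia response list had a median of -0.129 (camera adjusted p = 0.0492; adjusted p = 0.494 with an estimated correlation; 0 adjusted over the list alone), with Ndrg1 at -0.41. Its call was kept without wild-type SB replicate 2 (median -0.08), wild-type VILI replicate 3 (-0.21) or knockout SB replicate 2, and lost without each of the other 9 arrays: wild-type SB replicate 1 (0.0889) and 3 (0.0564), wild-type VILI replicate 1 (0.0556) and 2 (0.0745), knockout SB replicate 1 (0.166) and 3 (0.108), and knockout VILI replicate 1 (0.136), 2 (0.052) and 3 (0.058).

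Of 100 splits drawn from the 200 possible with the genotypes exchanged within SB and within VILI, 48 gave 7 or more shifted lists, and the highest of the other splits gave 18. Chance cannot be excluded for the number of lists. For single genes the real count is 0, so all 100 splits give at least as many and this says nothing on chance. The highest of the others gave 134, which points to a structure of the samples.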

How the results depend on the processing

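The second array weight estimate and the fits without 2 arrays are tests chosen after the result was seen. Of the counts and summary values under an alternative 266 stayed within 1.5 times or on the same side of the threshold, 77 moved, 1 became stronger and 4 changed direction. Of the medians of passed lists 257 kept their call, 120 lost it and 1 changed direction, and of the named gene values 1063 kept their side of the threshold, 105 lost the call, 11 came to pass and 4 changed direction. For lists and named genes, only the lowest and the highest value of the fits that left out 1 array entered these tallies. They therefore understate how often a call was lost, as Igha under VILI lost its call in 11 of 12 such fits. With array weights 4244 genes changed in wild type, 5522 in knockout, 171 in the difference of responses, 102 between genotypes under SB and 852 under VILI, but this estimate stopped before convergence. The gene-by-gene estimate of the weights gave 3836, 4017, 1, 26 and 84. With only the groups compared 845 genes changed in wild type and 0 between genotypes under SB. Without the dim filter the difference of responses had 1 gene and the genotypes under VILI 6, with a 60th percentile filter the latter had 8, and testing every probe set gave 7191 for the mean VILI response. The replicate block left 0 genes between genotypes under SB and 2 under VILI, and 3 lists for the difference of responses and 2 between genotypes under VILI. Of 18 pairs of arrays with the same replicate number 3 correlated above 0.1, from -0.628 to 0.398. With both SB arrays that stand apart left out the difference of responses had 11 genes and 12 lists, and the genotypes differed in 19 genes under SB and 28 under VILI. With wild-type SB replicates 1 and 2 left out, which leaves 1 wild-type SB array, the difference had 27 genes and 11 lists, the genotypes differed in 65 genes under SB and in 5 lists under VILI. That fit takes its spread from the other groups alone, so these counts are no test of wild type under SB. In it the median of club cell markers under SB was 0 (adjusted p = 0.703), and Il1b and Il1a in wild type were at -0.076 and -0.055. The Il1b difference was -0.024 without both arrays that stand apart and from -0.035 to 1.614 with 1 array left out. Camera with an estimated correlation found 0 lists in each of the 5 comparisons, and fry 0 in the difference and in both genotype comparisons but 11 in each VILI comparison. Quantile normalization gave 4 lists for the difference and 3 between genotypes under VILI, where no dim filter gave 5. The damping value was -0.162 without wild-type SB replicates 1 and 2. It was -0.112 over all genes called in wild type (exact permutation p = 0.165) and 0.165 over all genes called in knockout (exact permutation p = 0.035). Both sets include the genes called in both genotypes, and these gene choices favour opposite directions by construction. Leaving out 1 array at a time gave 933 to 2052 genes in wild type, 1232 to 3301 in knockout, 0 to 6 in the difference, 0 to 16 between genotypes under SB and 2 to 19 under VILI. It gave 13 to 17 lists in wild type, 10 to 14 in knockout, 2 to 11 in the difference, 6 to 11 between genotypes under SB and 1 to 7 under VILI, and a damping value of -0.022 to 0.118. The cause of these changes was not tested, apart from the opposite selection of genes. No pseudocount was varied, since the values are on a log2 scale. Signal near the background compresses the differences of dim genes in these arrays, so small changes of genes near the filter level can be missed.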

Other observations

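Parts of the response not described above concern the pathway of the targeted kinase. In the actomyosin and MLCK pathway list 3 of 21 members rose in wild type under VILI and none fell (4 rose and 2 fell adjusted over the list alone), and in knockout 6 rose and 1 fell (8 and 2 adjusted over the list alone). By camera the list did not shift in either (camera adjusted p = 0.132 and 0.0653). It passed fry in knockout (fry adjusted p = 0.0195) and not in wild type (fry adjusted p = 0.0984). Endothelial markers and junctions had 1 that rose and 6 that fell in knockout, with a median of -0.25, and did not shift by camera either (camera adjusted p = 0.138). That list passed fry in knockout (fry adjusted p = 0.00254) and in wild type (fry adjusted p = 0.00465). Of the genes called in wild type, 1540 (81.4%) passed an unadjusted p under 0.05 with the same sign in knockout, and of those called in knockout 1839 (72%) did so in wild type. The differences between genotypes under SB and under VILI correlated at 0.1519 across genes.

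In this part the tests of placement on the chromosome, of called genes there with 1 probe set, of array positions, of the glucocorticoid list and of the other probe sets of the 6 genes that set wild-type SB replicates 1 and 2 apart were chosen after the result was seen.

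Genes that differed between the genotypes gathered on the chromosome that carries Mylk. Of 15 genes called in either genotype comparison 6 lie there (40%), against 394 of 12266 tested (3.212%). Fisher's exact test against random placement gave p = 4.14e-06. It takes genes as independent, which linked genes are not, and was chosen after the result was seen, so its p is no exact measure of chance. By the order of tested genes in GRCm38.p6 the 6 genes lie 36 (Upk1b), 42 (Atp13a4), 52 (Slc35a5), 69 (Dubr), 91 (Gp1bb) and 162 (Clec16a) genes from Mylk. The planned list of Mylk with 21 tested neighbours had medians of -0.05 under SB and -0.07 under VILI, with no member past the threshold, and did not shift (camera adjusted p = 0.262 and 0.382). For Upk1b and Slc35a5 the other probe sets had a median of 0.9343 of the called difference (quartiles 0.6448 to 1.134), which argues against sequence variants under single probe sets for Upk1b (0.7772 to 1.203) more than for Slc35a5 (0.2419 to 2.023). The other 4 genes have no other probe set, so variants under their probes cannot be told apart from changed expression, and an effect of the targeted gene and a segment of the strain in which the gene was targeted both stay open, since neighbours in such a segment need not differ in expression.

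The SB arrays wild-type replicate 3 and knockout replicate 2 stand apart from the other SB arrays alike. Mislabelled VILI arrays are excluded, since on an axis from the other SB arrays (0) to the VILI arrays (1) the higher of the 2 lay at 0.1277. A shift of the whole distribution cannot be tested, since the deposited values are already normalized between arrays and the correlation of the 2 arrays' deviations, 0.706 before and 0.7069 after quantile normalization, leaves such a shift out. The glucocorticoid list lay -1.16 and -1.177 from the other SB arrays, at percentile 0 of 10000 random lists in both, but the list was chosen because it was seen to be low, so this decides nothing on lower glucocorticoid exposure of those animals. The NRF2 list is low in the same arrays, and no biological explanation from the design was tested, since the arrays come from both genotypes.

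Wild-type SB replicates 1 and 2 differ from the other 10 arrays in 6 genes on 5 chromosomes, none of them that of Mylk, by a gap above 0.8 log2, and of 66 pairs of arrays only this pair and the 2 arrays above (110 genes) had as many, and any other had at most 1. The other probe sets of 5 of these genes past the filter had a pooled median of 0.9539 of the difference. This argues against variants under single probe sets for Sox11 (1 of 5 had 0.1023) and Wdfy1 (1.004 and 0.8047, with dim ones at -0.013 and 0.174 left out). Cd59a and Rab4a had 1 other probe set each, at 1.451 and 1.958, which points the same way but is too few to exclude variants. For the other 2 genes such variants stay open, as the probe sets of Fank1 had 0.1134 and 0.3824 and Mboat2 has none past the filter. Segments of another strain around these genes cannot be told from their neighbours, whose median difference of 0.1741 lay at percentile 57.05 of random places (0.1336 to 0.2133). The labels give all animals as C57BL/6, and 1 of the 6 genes (Rab4a, -0.69, adjusted p = 0.0476) is among those changed in wild type and none in knockout, though it lost its call in 11 of the 12 fits that left out 1 array (largest adjusted p = 0.155, without wild-type SB replicate 1).

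Splits of the 6 arrays of a 2-group comparison number 10, so a share under 0.05 cannot be reached. VILI against SB gave 1892 genes in wild type and 2554 in knockout, where the highest of the other splits gave 0 in both, so 1 of 10 splits was as large in each. For lists 2 of 10 splits gave as many as the 13 in wild type (highest other 14) and 3 of 10 as many as the 11 in knockout (highest other 12). In each other split 1 side still held more VILI arrays, so lists that respond to VILI could shift there too. These list counts therefore do not decide on chance. Between genotypes under SB 3 of 10 splits gave at least the 6 genes, and the highest other gave 642, which points to a structure of the samples, and for lists 2 of 10 gave 10 (highest other 10). Under VILI 1 of 10 gave 13 genes (highest other 1), and all 10 gave at least 1 list (highest other 5). For the mean VILI response 1 of 100 drawn splits gave as many as 4520 genes (highest other 10), so chance is excluded there.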
